A study of Homo sapiens with 24 samples.

How the data were processed

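The series held 24 libraries from the human embryonic stem cell line H9, 12 of polyadenylated RNA and 12 of small RNA. Per the labels, wild-type (WT) cells and cells carrying a stable short hairpin RNA against ADAR1 (the protein encoded by ADAR, an adenosine-to-inosine RNA editing enzyme) were collected at day 0, at day 10, and at days 17 and 35 of a forebrain and of a motor neuron protocol. There was 1 library for each line, stage and assay, so no stage had replicates, and 1 knockdown line stood against 1 WT line. Cells grew on irradiated mouse feeder cells, formed aggregates without FGF2, were moved to neural induction medium and attached to laminin. The motor neuron protocol added retinoic acid to the day 10 primitive neuroepithelium, and retinoic acid, purmorphamine and B27 after the definitive neuroepithelium was isolated. Libraries were made with Illumina TruSeq Stranded Total RNA and TruSeq Small kits per the labels.

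TopHat2 2.0.8, bedtools and the human assembly hg19 are named in the submitters' processing notes without their role or order. The gene and microRNA annotations, their versions and the use of strand in counting are not given in the sources used here. The deposited mRNA table gives a signal for each of 17435 gene symbols and 12 libraries. Its header names no unit. The values behave as read densities scaled by depth and gene length, with columns summing from 225425 to 300211. Relative depth, from the ratios shared by many weakly expressed genes, ran from 0.840 to 1.08 of the WT day 0 library, but read numbers were not recovered, so no counting interval is given. The deposited small RNA table gives 1919 mature microRNA entries in RPM, reads scaled to a fixed library total. Each column was a multiple of 1 step between 0.0631 and 0.166 RPM, and 100% of values were whole reads within 0.1 read. The totals behind the RPM ran from 6013150 reads (knockdown, day 17 motor neuron) to 15849500 reads (WT, day 35 forebrain), and the recovered microRNA reads from 4692151 to 11014953. One read therefore sets the limit of detection, and this covers counting error only. The small RNA columns of the second line are headed by a code, 4146, that no label gives. They were taken as the knockdown by elimination, and ADAR could not be checked in small RNA. The same table heads the last stage day 33, where the labels give day 35, and it is called day 35 here.

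Values were analysed as log2(value + 1), which understates the fold of genes near 0. Genes and microRNAs with a value of at least 1 in at least 2 of the 12 libraries were tested, 12985 genes and 909 microRNAs. The limma 3.58.1 moderated test in R 4.3.3 was fitted with the 6 stages as a block and the line as a term, at a Benjamini-Hochberg adjusted p of 0.05. Each stage thus served as a matched pair of a WT and a knockdown library, a pairing that rests on the stage given in the labels, since culture dates are not given. The same fit gave day 10 minus day 0, day 35 minus day 0 and motor neuron minus forebrain. Interaction terms asked whether the knockdown difference at day 0 differed from that at later stages, and whether it differed between protocols. All p-values are two-sided. For the knockdown, limma p-values measure how steadily a difference held over stages, with the residual scatter as error. For stages and protocols the WT and knockdown libraries of a stage served as its replicates, with the same scatter as error. The p-values of camera compare the genes of a list with the other genes. No p-value here measures variation between independent knockdown lines. Single stages were compared without a test, by genes at least 2-fold apart with at least 5 in the higher library.

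The comparisons, tests, 29 gene lists, 13 microRNA lists and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. At single stages, a list's median was ranked among those of 10000 random lists matched in size and mean expression. The named genes were ADAR, then, for the knockdown, those past the threshold with the same sign at all 6 stages and a mean of at least 5 in the higher line. Of these, the 12 largest each way were taken for mRNA and the 8 largest for small RNA. Where fewer than 5 qualified, the 6 with the smallest p were taken. For stages and protocols the 8 largest each way with the same sign in both lines were taken, for single stages the 5 largest each way with at least 20 in the higher library, and for lists up to 4 members with the smallest p. Names outside this rule are marked where they occur. Y-linked genes and XIST were left out.

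Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5, quantile normalization, median-of-ratios scaling, an intensity trend, no stage block, each stage left out, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered small RNA reads. Added after seeing the data were a fit without X-linked genes, fits without both forebrain stages, and small RNA totals without miR-10a and miR-10b or over listed microRNAs only. Gene neighbours came from the GRCh38.p14 annotation, in which 14762 symbols matched directly and 1971 by an older symbol (96.0% in all); no positions are given. Reads from the mouse feeder cells, and biases of base composition or length, were not assessed, as no genome sequence was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for matching, permutations and plots. The values of some single genes are not reported here.

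The model was tested on simulated data with the same design. Noise was drawn independently for each gene and library, so correlation between stages or between genes is not covered by these error rates. Differences of 0.5, 1 and 2 (log2) between lines were recovered for 21.4%, 93.7% and 98.5% of genes, with 3 false calls among 143, and for 33.3%, 94.9% and 100% of microRNAs, with 4 false calls among 166. For day 10 minus day 0 the recovery of genes was 4.76%, 30.3% and 95.8%, and for motor neuron minus forebrain 12.5%, 77.4% and 100%, with 14 false calls among 144. The small RNA fits of these comparisons recovered 2.99%, 34.8% and 98.5%, and 18.1%, 78.1% and 100%. On simulated reads, edgeR recovered 6.35%, 66.7% and 93.2% of knockdown differences and DESeq2 11.1%, 65.1% and 87.8%.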

Results

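Polyadenylated and small RNA were profiled in 24 libraries of H9 human embryonic stem cells and of neural cells derived from them, 12 libraries for each assay. WT cells and cells with a stable ADAR1 knockdown were followed from the undifferentiated state at day 0 through primitive neuroepithelium at day 10 to days 17 and 35 of a forebrain or a motor neuron protocol. Each line had 1 library per stage, 6 stages in all. The series states its aim as learning what ADAR1 does in neural induction. Columns of the mRNA table summed from 225425 in the knockdown day 35 motor neuron library to 300211 in the WT day 0 library, and small RNA totals ran from 6013150 to 15849500 reads. Values below are the mRNA signal or microRNA RPM, differences are log2, and errors are standard errors of the fit unless stated. Since no stage had replicates, the spread of the knockdown difference over the 6 stages is the error of these fits.

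The first question was how far ADAR had fallen. ADAR stood at 65.2, 42.5, 35.4, 35.0, 39.9 and 38.5 in WT cells at day 0, day 10, day 17 forebrain, day 17 motor neuron, day 35 forebrain and day 35 motor neuron. In the knockdown line it stood at 10.0, 18.0, 16.4, 12.7, 10.8 and 12.4. It fell by 1.60 ± 0.19 on the log2 scale, lower at 6 of 6 stages (limma adjusted p = 0.0197). The other measured members of the family differed by less: ADARB1, a second adenosine deaminase, by 0.06, ADAT1 by −0.11 and ADAT2 by 0.11 (adjusted p = 0.729, 0.639 and 0.758), so the 4-member ADAR family list had 1 lower gene, and 1 adjusted over the list alone. The list median was −0.02 as deposited and 0.01 after quantile normalization, and the list test gave an adjusted p of 0.37. Leaving out 1 stage ended the ADAR call in 5 of the 6 cases, with adjusted p = 0.0667 without day 10, 0.0711 without day 17 forebrain, 0.108 without day 17 motor neuron, 0.0709 without day 35 forebrain and 0.0743 without day 35 motor neuron. Over all alternatives the fold lay between −1.71 and −1.37 and the adjusted p between 0.00318 and 0.24.

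**Figure D1:**
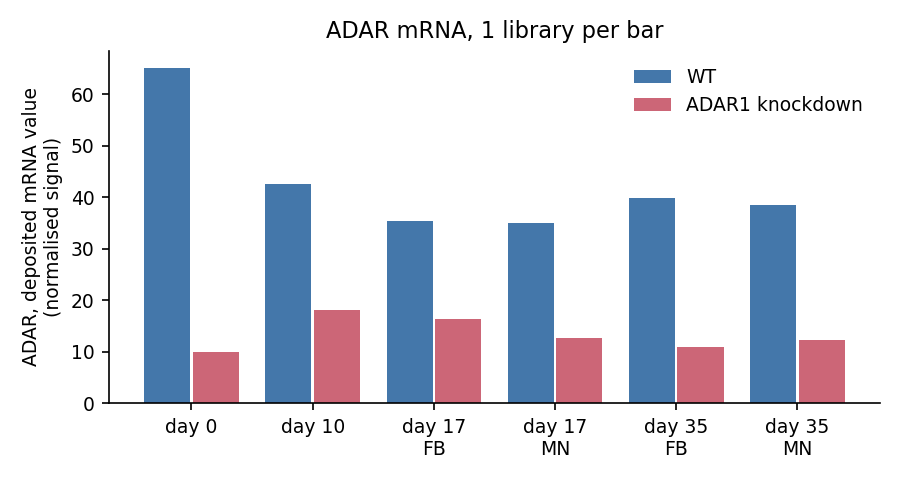
Bars give the ADAR mRNA signal (y axis, deposited units) of each library by stage (x axis), WT beside knockdown, with 1 library per bar and no error bars. The lowest WT value is 35.0 and the highest knockdown value 18.0.

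The second question was which other transcripts differed between the knockdown and WT lines over the 6 stages. The largest difference was in CRYZ, a quinone oxidoreductase, which stood at a mean of 8.21 in WT and 0.0478 in the knockdown line (−3.11 ± 0.12, n = 6 stages, adjusted p = 5.93e-05). PSMD5, a proteasome assembly chaperone, fell by 2.48 ± 0.27, the zinc finger gene ZNF880 fell by 1.63 ± 0.11 and THUMPD3, a tRNA methyltransferase, fell by 1.57 ± 0.11. They were followed by X-linked genes, namely HPRT1 (purine salvage) at −1.21, the phosphatase gene OCRL at −0.99, the chromatin factor PHF6 at −0.95 and the palmitoyltransferase ZDHHC9 at −0.88. Higher in the knockdown line were ADM, the vasoactive peptide adrenomedullin (1.40 ± 0.19, 7.38 against 3.18), the Rab escort protein gene CHM (1.01 ± 0.07, 4.95 in WT), the phosphoinositide phosphatase gene MTM1 (1.01 ± 0.10) and ACOT9, an acyl-CoA thioesterase (1.00 ± 0.14). All of these pointed the same way at 6 of 6 stages.

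In all, 34 of 12985 genes were called, 15 higher and 19 lower, and 2057 had an unadjusted p under 0.05. The remaining named genes were IDS (0.89), CXorf40B (0.85), PUS7L (0.84), SNORD107 (0.84), MTMR1 (0.78), FANCB (0.72), TMEM185A (0.72) and SNORD108 (0.69), and on the lower side LOC440905 (−2.37), SMARCA1 (−0.85) and AIFM1 (−0.85). CXorf40B has the near-identical copy CXorf40A, and SNORD107 and SNORD108 lie in the SNRPN host transcript region, so reads of these 3 entries were uncertain in origin. Of the 33 called genes with a place in GRCh38.p14, 16 were on the X chromosome, which held 506 of the 12615 tested genes with a place (Fisher's exact p = 2.21e-14, odds ratio 23.2). Groups of 5, 4 and 3 of these lay near each other with the same direction. The genes were thus not independent and this p is too small. Without X-linked genes 13 genes were called, 2 higher and 11 lower. The count depended on single stages: it was 64 without day 0, 9 without day 10, 9 without day 17 forebrain, 9 without day 17 motor neuron and 19 without day 35 motor neuron. It was also 2 without both forebrain stages.

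**Figure D2:**
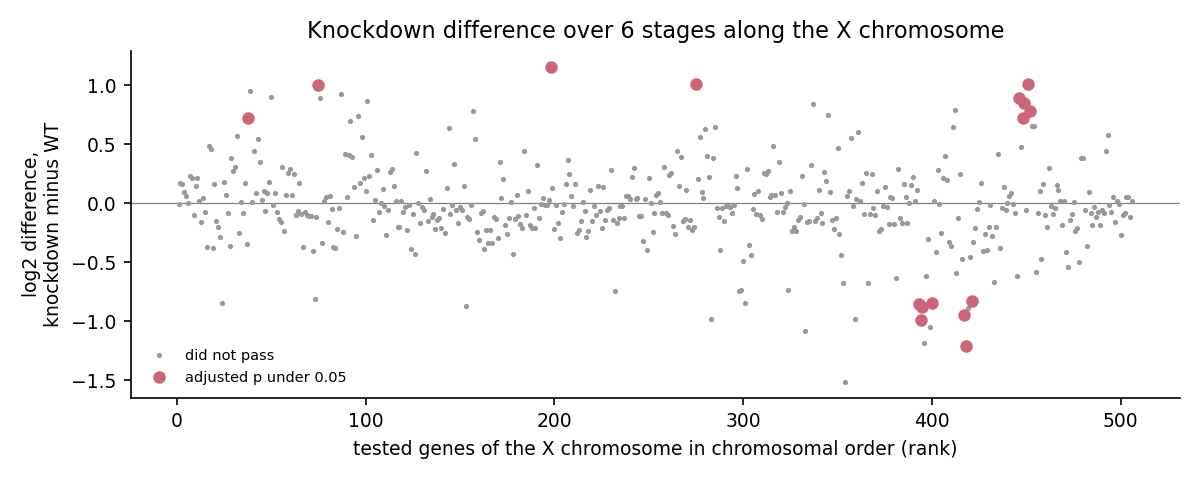
Each point is 1 of 506 tested X-linked genes, placed by its order on the chromosome (x axis, rank) against its knockdown minus WT log2 difference over 6 stages (y axis), with the 16 called genes marked. Of the 16, 12 lie in 3 stretches of one direction, such as OCRL (−0.99) beside ZDHHC9 (−0.88), and 4 stand alone, such as CHM (1.01).

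Pluripotency and neuronal gene lists, fixed in advance, leaned in opposite directions. All 22 measured pluripotency genes had positive differences (median 0.37, camera adjusted p = 5.95e-08), and the adjusted p was 0.277 with an estimated correlation. No member was called over all genes and 2 were adjusted over the list alone, DPPA4 (1.26) and DPPA2 (0.52), chromatin-associated genes of pluripotent cells. All 25 neurogenesis genes had negative differences (median −0.62, adjusted p = 1.08e-06, against an adjusted p of 0.395 with an estimated correlation), with DCX, a microtubule protein of young neurons, at −1.52 and SOX11 at −0.48. The 30 genes of mature neurons and synapses were negative as well (median −0.41, adjusted p = 0.000308, against an adjusted p of 0.511 with an estimated correlation), and 0 members of either list were called by limma over all genes or adjusted over the list alone. The mature neuron call ended without both forebrain stages (median −0.08, 10 of 30 positive, adjusted p = 0.926). The neurogenesis list was still called there at a smaller median (−0.28, 0.0116, against an adjusted p of 0.649 with an estimated correlation). The forebrain list was not called (median −0.27, adjusted p = 0.37; 1 lower gene adjusted over the list alone). The neuroectoderm list was not called either (median −0.09, adjusted p = 0.718), and its test pointed up where its median and mean were negative.

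Fixed lists named for other cell types leaned higher in the knockdown line. Some were also high in undifferentiated WT cells. The WT median level (log2) of epidermis was 3.89 at day 0 and 0.24 at day 35 forebrain. That of endothelium and blood was 4.43 and 0.32, while choroid plexus went the other way (0.07 and 1.90). A higher list therefore does not by itself show that other cell types were present. Of 25 mesenchyme, fibroblast and matrix genes 24 were positive (median 0.55, adjusted p = 3.9e-11), 9 were higher adjusted over the list alone and 0 over all genes, with TPM2 at 1.06 and S100A6 at 1.14. All 14 epidermis and surface ectoderm genes were positive (median 0.54, adjusted p = 6.47e-08), 4 of them higher adjusted over the list alone, including the keratins KRT18 (0.82) and KRT8 (0.87). Smaller called shifts were seen for retinoic acid and BMP-TGFb targets (median 0.41, 20 of 24 positive, adjusted p = 1.08e-06), neural crest (0.20, 0.00877), endothelium and blood (0.41, 0.01, with 1 gene adjusted over the list alone), trophoblast and amnion (0.20, 0.0267) and mesoderm (0.22, 0.0298, with 2 genes adjusted over the list alone). Each of these 7 lists had an adjusted p of 0.277 with an estimated correlation. Choroid plexus (0.21, 0.0133) and HOX and caudal genes (0.16, 0.0304) were called too, with an adjusted p of 0.543 and 0.405 with an estimated correlation. The neural crest, mesoderm, trophoblast, choroid plexus and HOX calls ended under quantile normalization (adjusted p from 0.0514 to 0.0792). Without both forebrain stages the choroid plexus list had 6 of 13 positive genes (camera adjusted p = 0.868), and the neural crest call ended too (0.04, 0.0678). The medians fell there to 0.16 for retinoic acid and BMP-TGFb targets and to 0.21 for endothelium and blood, while that of mesoderm rose to 0.32. At day 35 forebrain alone the choroid plexus median was 1.35. The glia list (median −0.04, 0.01 under median-of-ratios scaling), the endoderm list (median 0.13, mean −0.03) and the ventral spinal and motor neuron list (median −0.05, mean 0.03) were not called. The last was called higher without both forebrain stages (0.23, 0.000642, against an adjusted p of 0.286 with an estimated correlation).

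Stress and interferon genes were looked at next. Of 18 interferon-stimulated genes 15 were positive (median 0.20, adjusted p = 8.52e-05, against an adjusted p of 0.281 with an estimated correlation). Over all genes 0 were called by limma, and adjusted over the list alone 4 were higher and 1 lower, the higher ones being IFIT1 (0.72, adjusted p over all genes 0.0562), IFITM1 (1.07), TRIM22 (0.87) and PARP14 (0.39). The lean of the interferon-stimulated list was not steady over single stages. Its median was 0.25 at day 0, 0.33 at day 10, 0.17 at day 17 forebrain and 0.65 at day 35 forebrain. In the motor neuron protocol it was −0.02 at day 17 and −0.04 at day 35 (percentiles 74.8 and 90.8 among random lists). The double-stranded RNA sensing list was not called (median −0.05, adjusted p = 0.548). HLA and antigen presentation (median 0.33, adjusted p = 0.00636, against an adjusted p of 0.281 with an estimated correlation) had 1 gene adjusted over the list alone. Glycolysis and hypoxia genes were higher as a list (median 0.20, adjusted p = 8.52e-05, ADM called, against an adjusted p of 0.277 with an estimated correlation), as were p53 and apoptosis genes (0.21, 0.000502, against an adjusted p of 0.5 with an estimated correlation) and integrated stress response genes (0.19, 0.00206, against an adjusted p of 0.506 with an estimated correlation). Proliferation genes were lower (median −0.19, adjusted p = 0.00159, against an adjusted p of 0.277 with an estimated correlation), 3 of them adjusted over the list alone, PCNA (−0.40), RRM2 (−0.44) and TPX2 (−0.33). Ribosomal proteins (0.01), oxidative phosphorylation (−0.08), microRNA biogenesis (−0.08) and imprinted genes (−0.08, with H19 the 1 higher gene adjusted over the list alone) were not called, with adjusted p of 0.399, 0.215, 0.148 and 0.69. Without both forebrain stages the medians were 0.32 for pluripotency, 0.25 for mesenchyme and 0.09 for interferon-stimulated genes, all 3 still called, with an adjusted p of 0.286, 0.321 and 0.393 with an estimated correlation. The integrated stress response call ended there (median −0.03, 10 of 24 positive, camera adjusted p = 0.841). Medians fell to 0.17 for HLA and antigen presentation and to 0.09 for p53 and apoptosis, while that of glycolysis and hypoxia rose to 0.27. Oxidative phosphorylation was called lower in that fit (−0.10, 0.0155, against an adjusted p of 0.649 with an estimated correlation).

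Among small RNAs, microRNAs of the miR-302 cluster, which includes miR-367, which mark pluripotent cells, were higher in the knockdown line. miR-302c-3p was higher by 1.92 ± 0.36, miR-302b-3p by 1.88 ± 0.31, miR-302a-5p by 1.86 ± 0.38, miR-302d-3p by 1.75 ± 0.35 and miR-302a-3p by 1.71 ± 0.32, each at 6 of 6 stages (adjusted p from 0.0373 to 0.0404). All 10 cluster members were positive (median 1.61, adjusted p = 7.16e-07, against an adjusted p of 0.446 with an estimated correlation), 5 called over all microRNAs and 9 adjusted over the list alone; reads of these closely related sequences can be assigned to the wrong member. miR-361-5p, which lies in an intron of CHM, was higher by 1.36 ± 0.14 (822 against 325 RPM, adjusted p = 0.00309), miR-3663-3p by 1.62 and miR-31-5p by 1.32. Lower were miR-3065-5p (−1.17 ± 0.21), miR-3939 (−1.18), miR-376a-5p (−0.98), miR-1269b (−0.81) and miR-3174 (−0.68), while miR-1269a stood at −0.87 and missed the threshold (adjusted p = 0.0514). Only 3 lower microRNAs met the rule for naming, so the 6 with the smallest p are given. miR-9-5p, a microRNA of neural progenitors and neurons, stood at −2.03 ± 0.50 (adjusted p = 0.0597).

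Over all microRNAs 21 of 909 were called, 16 higher and 5 lower, and 226 had an unadjusted p under 0.05. The median of all microRNAs was itself 0.11 higher in the knockdown line, and under quantile normalization the split was 10 higher and 7 lower, under median-of-ratios scaling 2 higher and 3 lower. With edgeR 20 were called (14 of them among the 21) and with DESeq2 92. The count was 1 without day 10, 1 without day 17 forebrain, 1 without day 17 motor neuron, 51 without day 35 forebrain, 1 without day 35 motor neuron, 1 without both forebrain stages and 0 in limma without the stage block. Higher as lists were the chromosome 19 cluster (C19MC, a primate cluster of placenta and stem cells; 55 of 57 positive, median 0.39, adjusted p = 7.16e-07), mesenchymal microRNAs (27 of 31 positive, median 0.65, 9.31e-05, with 14 adjusted over the list alone and 0 over all by limma) and epithelial microRNAs (median 0.49, 0.0427, with 2 adjusted over the list alone). Each of these 3 had an adjusted p of 0.454 with an estimated correlation. The chromosome 19 cluster was near 0 at day 35, with median levels in WT of 0.06 RPM (forebrain) and 0.08 RPM (motor neuron). In the knockdown line they were 0 and 0.32 RPM, so its differences there rest on few reads. The blood and endothelium list was higher (median 0.30, 0.0382) with miR-126-5p called, an adjusted p of 0.446 with an estimated correlation and 0.11 under quantile normalization. Lower were let-7 and miR-98, a family that accumulates with differentiation (13 of 14 negative, median −0.53, camera adjusted p = 7.55e-05, and 0.454 with an estimated correlation). Also lower were the chromosome 14 DLK1-DIO3 cluster (median −0.29, 1.42e-11), neural microRNAs (median −0.30, 8.7e-06), miR-17-92 and paralogs (−0.13, 0.00136) and mirtrons (−0.18, 0.00542). These last 4 had an adjusted p of 0.446 with an estimated correlation. Under quantile normalization and median-of-ratios scaling the miR-17-92 median was −0.24 and −0.27, and that of mirtrons −0.31 and −0.32. Without both forebrain stages 5 of these calls ended, namely neural (median −0.01, 19 of 42 positive, adjusted p = 0.35), let-7 (−0.14, 0.086), mesenchymal (0.28, 0.0866), blood and endothelium (0.30, 0.152) and mirtrons (−0.14, 0.0835). The miR-302, chromosome 19, epithelial, chromosome 14 and miR-17-92 lists were still called (1.15, 0.34, 0.57, −0.37 and −0.26), each with an adjusted p of 0.395 with an estimated correlation. The miR-371-373 cluster (−0.23), HOX-embedded microRNAs (0.32) and muscle microRNAs (0.12, −0.01 under median-of-ratios scaling) were not called. The miR-371-373 cluster differed in sign by stage. Its median was 0.50 at day 0, −1.45 at day 10, −1.15 at day 17 forebrain, 0.56 at day 17 motor neuron, −0.29 at day 35 forebrain and 0.49 at day 35 motor neuron. Only day 10 and day 17 forebrain, both lower, stood out from random lists (percentiles 0.01 and 1.15). The other stages lay between percentiles 5.99 and 95.7. At day 35 motor neuron the median levels were only 0.08 RPM in WT and 0.40 RPM in the knockdown library.

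**Figure D3:**
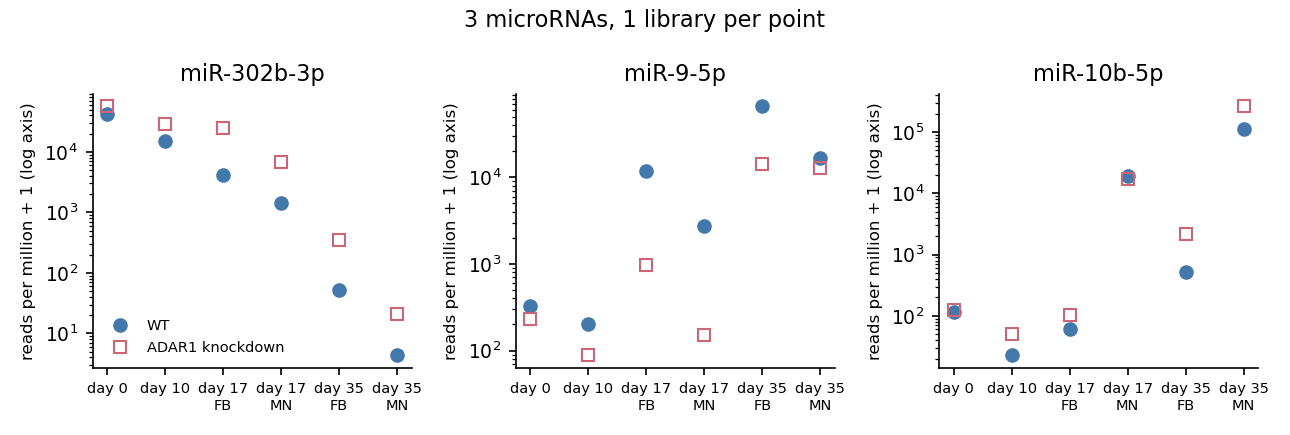
Points give the RPM plus 1 (y axis, log scale) of miR-302b-3p, miR-9-5p and miR-10b-5p over the 6 stages (x axis), filled circles for WT and open squares for the knockdown, 1 library per point. At day 17 of the forebrain protocol miR-9-5p stood at 11994 RPM in WT and 975 RPM in the knockdown library.

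At single stages, where 1 library stood against 1 and no test was possible, genes at least 2-fold apart numbered 94 at day 0 (83 higher in the knockdown library), 132 at day 10 (99 higher), 369 at day 17 forebrain (181 higher), 134 at day 17 motor neuron (75 higher), 1012 at day 35 forebrain (495 higher) and 513 at day 35 motor neuron (90 higher). Day 0 held the fewest, led by ADAR (65.2 in WT, 10.0 in the knockdown), HPRT1 and the WNT antagonist SFRP1 (62.4 and 27.9) on the lower side and by RPS15 (21.3 and 80.7) and CLC (5.99 and 28.7) on the higher. At day 17 forebrain, STMN2, a microtubule regulator of growing axons, stood at 101 and 6.57, the pluripotency-associated L1TD1 at 11.8 and 89.0 and the retinoic acid hydroxylase CYP26A1 at 2.25 and 22.3. At day 17 motor neuron STMN2 stood at 31.0 and 1.15, and the growth factor PTN at 58.4 and 262. At day 35 forebrain the neuropeptide gene TAC1 stood at 99.4 and 1.60 and the interneuron regulator DLX1 at 43.1 and 1.01, with ANKRD1 at 3.80 and 130 and CTGF at 9.28 and 154. At day 35 motor neuron DPPA4 stood at 5.53 and 33.9, CRABP1 (retinoic acid binding) at 459 and 83.2 and RPS15 at 49.6 and 9.13. The median of all genes there was −0.16 as deposited and 0.01 after quantile normalization, which changed the split from 90 higher and 423 lower to 153 and 241.

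List medians at single stages traced the same groups. The pluripotency list stood at 0.20 at day 0 (percentile 99.6 among random lists), 0.59 at day 10, 1.24 at day 17 forebrain (percentile 100) and 0.25 at day 17 motor neuron. It stood at 0.02 at day 35 forebrain (percentile 61.1) and at 0.08 at day 35 motor neuron (percentile 99.6). The last percentile carries little, because the median values there were 0.30 in WT and 0.54 in the knockdown library, near the floor. Random lists, matched on the mean over all libraries, mostly ran from −0.39 to 0.01 there, with an all-gene median of −0.16. The neurogenesis list stood at 0.08 at day 0 (19 of 25 positive), 0.01 at day 10, −1.40 at day 17 forebrain, −1.15 at day 17 motor neuron and −1.10 at day 35 forebrain, the last 3 below all random lists, and at −0.32 at day 35 motor neuron (percentile 11). The mature neuron list stood at 0.16 at day 0 (25 of 30 positive), 0.12 at day 10, −0.48 at day 17 forebrain and −0.21 at day 17 motor neuron. It reached −1.52 and the mesenchyme list 1.56 at day 35 forebrain, against −0.41 and −0.05 at day 35 motor neuron. The p53 and apoptosis list stood at 0.46, 0.01, −0.04, −0.33, 0.95 and 0.18 at the 6 stages in order. The glycolysis and hypoxia list stood at 0.29, 0.29, 0.22, −0.05, −0.32 and 0.51. The ribosomal protein list stood at 0.30 at day 0, 0.49 at day 10, 0.06 at day 17 forebrain, −0.26 at day 17 motor neuron, 0.47 at day 35 forebrain and −1.02 at day 35 motor neuron. For small RNAs, 29, 50, 138, 70, 182 and 83 microRNAs were at least 2-fold apart at the 6 stages in the same order, and the miR-302 list stood at 0.42, 0.88, 2.72, 2.12, 2.58 and 1.09. The chromosome 14 list stood at −0.56 at day 10, −0.65 at day 17 forebrain, −0.48 at day 17 motor neuron and −0.43 at day 35 motor neuron. It stood at 0 at day 0, where the median level was 0 RPM in both lines, so that a difference could hardly be measured. At day 35 forebrain it stood at 0.39 (54 of 62 positive). The all-microRNA median was 0.13 at day 0, 0.14 at day 10 and 0.12 at day 35 forebrain. miR-9-5p stood at 2778 and 149 RPM at day 17 motor neuron, miR-138-5p at 878 and 47.8 RPM and miR-21-3p at 199 and 1723 RPM at day 35 forebrain, and miR-200b-3p at 245 and 885 RPM at day 0. By correlation over all genes the knockdown day 17 forebrain library lay closer to WT day 10 (r = 0.970) than to its own stage (0.965), and the knockdown day 35 forebrain library closer to WT day 17 motor neuron (0.955) than to its own stage (0.921). In small RNA the first stood at 0.970 with WT day 10 and 0.969 with its own stage. The second lay nearest its own stage (0.966, against 0.955 for WT day 17 motor neuron).

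**Figure D4:**
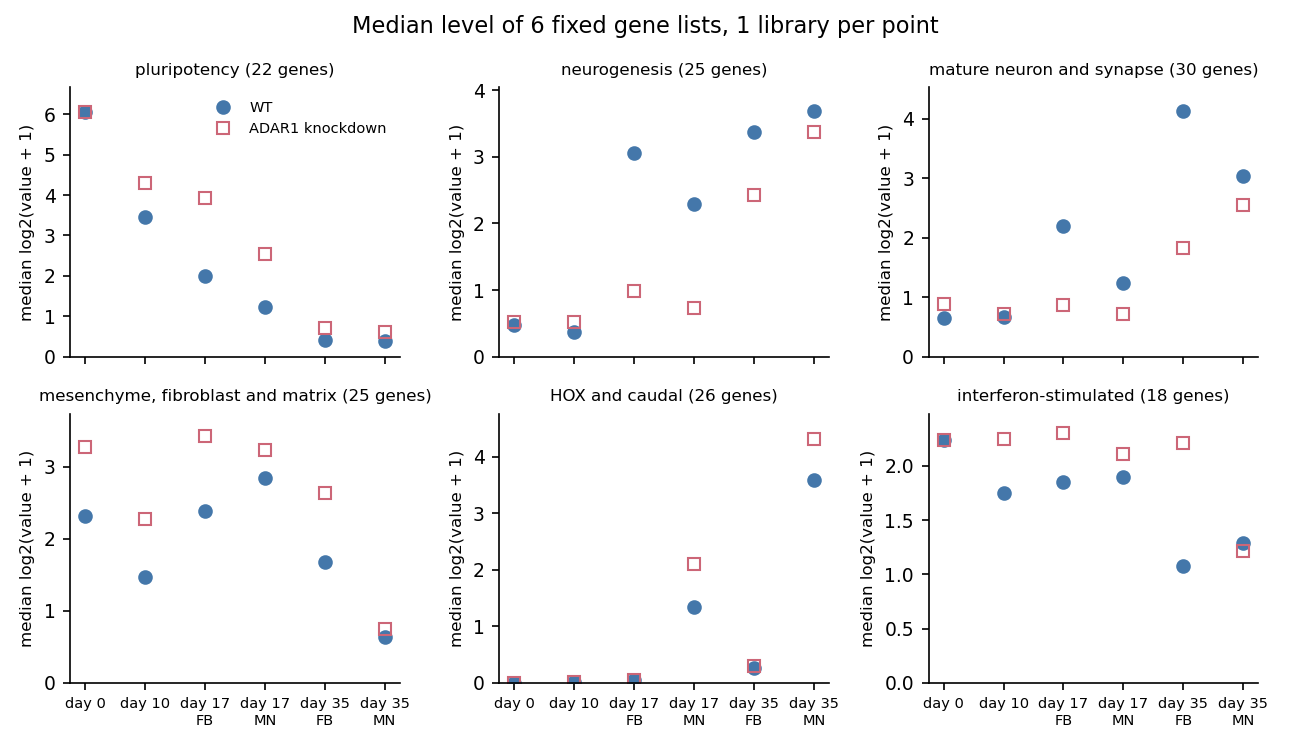
Points give the median log2(value + 1) of 6 fixed lists (y axis) over the 6 stages (x axis), filled circles for WT and open squares for the knockdown, 1 library per point. At day 17 of the forebrain protocol the pluripotency median was 2.00 in WT and 3.92 in the knockdown library, and the neurogenesis median 3.05 and 0.99.

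Whether the knockdown difference itself changed with stage or protocol was asked with interaction terms. Day 0 held 1 library per line, so the spread of its own difference is unknown and the error came from the later stages. For mRNA limma called 0 genes for day 0 against later stages (282 at an unadjusted p under 0.05) and 0 for motor neuron against forebrain (1456 at an unadjusted p under 0.05). The pluripotency list was nonetheless called for day 0 against later stages (median −0.36, adjusted p = 0.0454, against an adjusted p of 0.887 with an estimated correlation and 0.392 under quantile normalization), and the neurogenesis list as well (median 0.93, 9.02e-06, against an adjusted p of 0.887 with an estimated correlation). Between protocols the knockdown difference of neurogenesis genes was 0.74 higher in motor neuron than in forebrain cultures (7.53e-09, against an adjusted p of 0.422 with an estimated correlation) and that of mesenchyme genes stood at −0.93 (5.85e-07, against an adjusted p of 0.431 with an estimated correlation). For small RNA limma called 0 in both comparisons (42 and 50 at an unadjusted p under 0.05), as did edgeR (0 and 0) and DESeq2 (0 and 0), while the miR-302 list was called in both (medians −1.50 and −0.95, adjusted p = 4.25e-06 and 6.11e-05, against an adjusted p of 0.5 and 0.514 with an estimated correlation). Leaving out day 17 forebrain left day 35 forebrain as the only forebrain pair. The spread of its knockdown difference is then unknown, so no count is given for this interaction.

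The course of differentiation, common to both lines, was described from day 0 to day 10. Genes of early neural fate rose: SIX3, a regulator of anterior neural fate, by 5.71 ± 0.24 (54.0 against 0.0135, 2 libraries each), the receptor gene EPHA4 by 5.06 ± 0.32, PRTG by 5.79 ± 0.56 and MAP2 by 5.01 ± 0.37. DLK1, an imprinted NOTCH pathway gene, rose by 6.48 ± 0.77, GREB1L by 5.83, the WNT antagonist FRZB by 5.77 and IGFBP5 by 5.44. The largest falls were those of the NODAL pathway gene LEFTY1 from 107 to 0.0454 (−6.69 ± 0.14), the neuropeptide gene NTS by 4.98 ± 1.10 and S100A10 by 4.82 ± 0.31, followed by ACTA1 (−4.52), SERPINB9 (−4.52), TAGLN (−4.48), LOC100131138 (−4.40) and GRPR (−4.31). Of 29 neuroectoderm genes 21 rose (26 adjusted over the list alone, with 1 lower), such as FEZF1 (4.39) and ZNF521 (4.12), and of 22 forebrain genes 11 rose (11 adjusted over the list alone), such as LMO3 (4.00) and LHX2 (4.48). Of 22 pluripotency genes 14 fell and 1 rose (15 and 1 adjusted over the list alone), with NANOG at −3.94 and NODAL at −2.82. The adjusted p of these 3 lists was 6.94e-11, 5.2e-05 and 2.95e-07, and 0.302, 0.237 and 0.314 with an estimated correlation.

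In all 2159 genes rose and 1680 fell from day 0 to day 10, of 5429 at an unadjusted p under 0.05. Called lower as lists were epidermis (median −1.54), mesenchyme (−0.96), integrated stress response (−0.99), p53 and apoptosis (−0.89), glycolysis (−0.55), oxidative phosphorylation (−0.55), HLA (−0.72), mesoderm (−1.25) and endothelium (−2.23), and higher were imprinted genes (0.83), with an adjusted p from 0.314 to 0.678 with an estimated correlation. The retinoic acid and BMP-TGFb list (median 0.49, mean −0.05) and the mature neuron list (median −0.05, mean 0.08) differed in sign between median and mean and were not called. Among microRNAs 206 rose and 223 fell (485 at an unadjusted p under 0.05). All 62 measured members of the chromosome 14 cluster rose (median 3.55, adjusted p = 1e-32), among them miR-654-3p (8.01 ± 0.34), miR-127-3p (7.63 ± 0.36), miR-411-5p (7.53), miR-410 (7.24), miR-409-3p (7.19) and miR-381 (7.02), and all 57 of the chromosome 19 cluster fell (median −3.19, adjusted p = 6.69e-29), among them miR-515-5p (−4.30 ± 0.43), miR-518b (−4.15), miR-498 (−4.01) and miR-519c-3p (−3.95). Both clusters had the same counts adjusted over the list alone, and an adjusted p of 0.311 with an estimated correlation. Outside them miR-1247-3p (7.63) and miR-3663-3p (7.11) rose and miR-548f (−4.21), miR-3943 (−4.06), miR-424-5p (−4.02) and miR-4435 (−3.95) fell. Of 11 epithelial microRNAs 10 fell (median −2.29, adjusted p = 0.0021, against an adjusted p of 0.656 with an estimated correlation), and miR-17-92 and paralogs were higher (median 0.54, 0.0166, against an adjusted p of 0.856 with an estimated correlation).

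By day 35 (4 libraries against 2) neuronal genes had risen and genes of pluripotency had fallen. STMN2 rose by 6.21 ± 1.09, DCX by 5.85 ± 0.63, MAP2 by 5.77 ± 0.32 and MAP6, a microtubule stabiliser, by 5.11 ± 0.28, beside DLK1 (5.39), ARRDC3 (5.29), LOC645323 (5.23) and MEIS2 (5.16). The non-coding transcript ESRG fell by 8.48 ± 0.47, while TDGF1, a NODAL co-receptor, stood at −8.43 ± 0.48 and L1TD1 at −8.21 ± 0.52, and LEFTY1 (−6.53), ZFP42 (−6.03), NANOG (−5.97), EPCAM (−5.93) and GRPR (−5.91) fell with them. Of 25 neurogenesis genes 22 rose (24 adjusted over the list alone; median 2.09), of 30 mature neuron genes 18 (18 alone; 1.62), of 26 HOX and caudal genes 22, with 1 lower (22 and 1 alone; 2.08), of 29 neuroectoderm genes 24 (2.30), of 22 forebrain genes 17 (1.85), of 15 ventral spinal genes 12 (1.55) and of 16 imprinted genes 14 (1.30). Of 22 pluripotency genes 20 fell (20 alone; median −4.00), and also lower were epidermis (12 of 14, −2.78), mesenchyme (14 of 25, with 4 higher, −0.84), interferon-stimulated (12 of 18, −1.02), HLA (5 of 6, −1.10), endothelium (3 of 3, −3.82), proliferation (16 of 30, −0.60) and oxidative phosphorylation genes (11 of 24, −0.55). These 15 lists were called, with an adjusted p from 0.209 to 0.665 with an estimated correlation, and the proliferation and oxidative phosphorylation calls ended under quantile normalization (adjusted p = 0.215 and 0.165). Over all genes 3946 rose and 3716 fell (8249 at an unadjusted p under 0.05).

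In small RNA at day 35 the miR-302 cluster fell in 10 of 10 members, by 11.15 ± 0.57 for miR-302a-5p and 11.10 ± 0.54 for miR-302c-3p, with miR-302d-3p at −11.04, miR-302a-3p at −10.80, miR-302b-3p at −10.42, miR-302c-5p at −10.39, miR-367-3p at −9.87 and miR-302d-5p at −8.99. miR-10a-5p, from within the HOXB cluster, rose by 10.30 ± 0.34, let-7c by 9.93 ± 0.56, miR-216b by 8.19, miR-99a-5p by 7.99, miR-217 by 7.78, miR-153 by 6.89, miR-125b-2-3p by 6.86, miR-10b-5p by 6.82 and miR-9-5p by 6.27. Of the fixed lists, let-7 (12 of 14 rose, median 3.39), neural (34 of 42, 2.48), HOX-embedded (5 of 6, 4.91) and chromosome 14 microRNAs (56 of 62, 57 adjusted over the list alone, 2.08) were higher. The chromosome 19 cluster (57 of 57, −6.28), miR-371-373 (5 of 5, −6.63), epithelial (11 of 11, −5.12), miR-17-92 (21 of 28, −1.15) and blood microRNAs (8 of 9, −1.95) were lower. With the miR-302 cluster (median −10.41) these were 10 called lists, with an adjusted p from 0.282 to 0.325 with an estimated correlation, and the muscle list, not called, had a median of −1.04 and a mean of 0.05. In all 232 rose and 413 fell (660 at an unadjusted p under 0.05). The median of all microRNAs was −0.47, and the split was 327 and 278 under quantile normalization and 292 and 326 under median-of-ratios scaling.

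Motor neuron and forebrain cultures were compared at days 17 and 35, 4 libraries each. Genes of hindbrain and spinal identity were higher in the motor neuron protocol: HOXB3 by 4.56 ± 0.18 (57.2 against 0.318), HOXB2 by 3.86 ± 0.18, HOXC4 by 3.66 ± 0.19 and the HOXA neighbour SKAP2 by 3.65 ± 0.31, with the non-coding transcripts FLJ12825 (4.11), LOC400043 (3.94) and LOC100240734 (3.80). Of 26 HOX and caudal genes 22 were higher (23 adjusted over the list alone; median 2.41, adjusted p = 4.16e-74, and an adjusted p of 0.00268 with an estimated correlation). Of 15 ventral spinal and motor neuron genes 8 were higher (11 adjusted over the list alone; median 0.90, 4.82e-22, against an adjusted p of 0.0897 with an estimated correlation), among them NKX2-2 (0.90) and the choline transporter SLC5A7 (2.18). Lower were TTR, a product of choroid plexus (−3.08 ± 0.26, 0.0523 against 42.2), the WNT pathway genes RSPO2 (−2.29), RSPO3 (−2.11) and WNT8B (−1.99), LIX1 (−2.05), CNTNAP2 (−1.55) and the forebrain regulator FEZF1 (−1.15). TTR rested on day 35, with 0.03 when either day 35 stage was left out.

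The lists lower in the motor neuron protocol were choroid plexus (4 of 13 genes lower, 8 adjusted over the list alone; median −1.11, adjusted p = 6.53e-11, against an adjusted p of 0.369 with an estimated correlation) and forebrain (3 lower and 1 higher, 9 and 1 adjusted over the list alone; −0.45, 0.000354, against an adjusted p of 0.134 with an estimated correlation). In the forebrain list OTX1 stood at −1.40 while NKX2-1, a ventral forebrain gene, was higher by 1.31. Also called lower were the lists of neuroectoderm (median −0.31), mesenchyme (−0.43), integrated stress response (−0.36), endothelium (−0.52) and mesoderm (−0.33), with an adjusted p from 1.22e-05 to 0.0444. Their adjusted p was 0.629, 0.629, 0.629, 0.397 and 0.369 with an estimated correlation. In all 93 genes were higher and 23 lower, of 1029 at an unadjusted p under 0.05. The count was 31 without day 35 forebrain and 30 without day 35 motor neuron, fits in which day 17 alone carried the comparison.

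HOX-embedded microRNAs were also higher in the motor neuron protocol: miR-10b-5p by 7.58 ± 0.34 and miR-10a-5p by 6.88 ± 0.28, which differ by 1 base in their middle and can exchange reads, then miR-615-3p (5.09), miR-10a-3p (4.96) and miR-10b-3p (4.74). Of the 6 listed members 5 were called and 6 adjusted over the list alone (median 5.02, adjusted p = 1.53e-30, and an adjusted p of 0.00237 with an estimated correlation). miR-219-2-3p (4.36), miR-133a (1.51) and miR-1 were higher as well. Lower were miR-449c-5p (−4.37 ± 0.33), miR-449a (−4.04 ± 0.58) and miR-449b-5p (−3.26 ± 0.44), a family of ciliated cells, miR-204-5p (−2.67 ± 0.37) and miR-302b-3p (−2.76 ± 0.39), miR-302d-3p (−2.67), miR-302a-3p (−2.61) and miR-302a-5p (−2.56). miR-204-5p stood at 0.21 when either day 35 stage was left out. The miR-302 list (8 of 10 lower, 9 adjusted over the list alone; median −2.17, 1.43e-05) and the muscle list (0.83, 0.00632) had an adjusted p of 0.59 with an estimated correlation. The median of all microRNAs was −0.31, and against it the chromosome 14 list (0.07, 5.63e-10, with an adjusted p of 0.76 with an estimated correlation) and the epithelial list (median 0.01, mean −0.03, 0.0356, with an adjusted p of 0.765 with an estimated correlation) tested up. The chromosome 19 list tested up at a median of −0.15 (0.0356, an adjusted p of 0.824 with an estimated correlation) and miR-17-92 tested down (−0.44, 0.0356, an adjusted p of 0.765 with an estimated correlation). The epithelial, chromosome 19 and miR-17-92 calls ended under quantile normalization (camera adjusted p = 0.471, 0.819 and 0.708). The chromosome 14 median was 0.42 under quantile normalization and 0.41 under median-of-ratios scaling.

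Over all microRNAs 13 were higher and 50 lower in the motor neuron protocol, with 273 at an unadjusted p under 0.05. Under quantile normalization the split was 16 and 16, under median-of-ratios scaling 16 and 16, with edgeR 14 and 18 and with DESeq2 24 and 29. miR-10a and miR-10b together took 55.0% of the total in WT and 55.5% in the knockdown day 35 motor neuron library, against 0.276% and 0.362% at day 35 forebrain. The count was 32 without day 10, 302 without day 17 forebrain, 259 without day 17 motor neuron, 19 without day 35 forebrain and 12 without day 35 motor neuron.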

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

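In this part the tests of chance placement of called genes, of undifferentiated cells, of wrong labels and an exchange, of the miR-10 share and of lower levels in the motor neuron protocol, and of the splits were chosen after the results were seen; the others were set before. Counts of interaction genes adjusted over each list alone are given as values.

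Genes called between the knockdown and WT lines often lay near each other on chromosomes. Of the 33 called genes with a place in GRCh38.p14, 18 had a called gene of the same direction within 10 tested genes, against at most 8 in 10000 random sets, which argues against chance placement. They formed 6 stretches: CRYZ with TYW3, SNORD107 with SNORD108, ZNF610 with ZNF880, and on the X chromosome IDS to MTMR1 (higher), SMARCA1 to AIFM1 (lower) and PHF6 to MOSPD1 (lower). Of 10 uncalled genes inside the stretches 9 leaned the same way, with a median of 0.66 in that direction. Random sets of single genes with random signs gave −0.14 to 0.14, but no stretches were drawn, so likeness between neighbours is not covered. Within IDS to MTMR1 1 of 2 leaned that way, CXorf40A, a near-identical copy of the called CXorf40B. The CRYZ and ZNF610 stretches held none. A difference between the lines in whole stretches, such as copy number or silencing, could give such values, and neither was measured. The 7 microRNAs between PHF6 and MOSPD1 did not follow their genes (median −0.04). Loss of ADAR acting on each gene by itself would make the stretch differences larger where more ADAR was lost. Over the 6 stages they ran the other way, smaller with a larger loss, at r = −0.68 (rho = −0.60, exact permutation p = 0.242; r = −0.93 without day 0 and day 17 forebrain), but with an exact permutation p = 0.126 over 6 stages this did not exclude it, and with 1 knockdown line the hairpin and the line cannot be told apart.

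The knockdown library of day 17 forebrain held genes of earlier stages, L1TD1 at 89.0 against 11.8 in WT. Undifferentiated cells as the source of the whole excess would raise all pluripotency genes alike. The 7 members at no more than 10% of day 0 in WT day 10 stood only 2.72% of the day 0 level above WT as a median. They ran from −1.12% to 5.27% (PRDM14 5.27%, NANOG 3.84%), against 19.5% for L1TD1, itself among the 5 largest rises of this library. By this criterion that argues against such cells as the only source. It replaced a first criterion after the values were seen. Over all 19 members the median was 12.6%, which did not argue against such cells, so the result rests on which members were taken. A share of a few percent stays open. A WT library or the motor neuron knockdown library of that day under its label is argued against by ADAR at 16.4, below the lowest WT value of 35.0, and by HOX genes 1.11 (log2) below that library. Neither value bears on an exchange with the day 10 knockdown library. That is argued against by the change from day 10 to day 17 forebrain, which ran the same way across genes in the knockdown line as in WT (r = 0.600, and 0.755 in small RNA), where an exchange would reverse it. A second sample of an early knockdown culture under this label stays open. Across genes, which are not independent replicates, the difference rose with WT day 10 minus WT day 17 motor neuron (r = 0.387). For the differences at day 0, day 35 forebrain and day 35 motor neuron r was −0.389, −0.0446 and 0.174. A culture at an earlier stage could give this. However, r at day 0 was as large with the opposite sign, so the value does not single that out. The miR-302 list, with medians of 3004 RPM in WT day 10, 809 in WT day 17 forebrain and 6574 in this library, went with an earlier stage. The miR-371-373 list (219, 58.8 and 24.9 RPM) went against it. Whether the knockdown or the culture set the stage of this library could not be tested with 1 library.

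Small RNA calls between protocols leaned lower, 50 of 63. With miR-10a and miR-10b out of the totals 63.9% of the calls pointed higher and the median of all microRNAs moved from −0.31 to 0.06, which suggests that a few microRNAs taking most of the reads at day 35 account for much of the lean. Of 14 microRNAs chosen in WT alone, at least 2-fold lower in the motor neuron protocol at both days in those totals, 9 (64.3%) were lower at both days in the knockdown line, against 17.1% of the others (Fisher's exact p = 0.00013, though microRNAs are not independent). This is consistent with lower levels in the motor neuron protocol itself for some microRNAs.

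Among the 32 ways of swapping the lines within stages, only the real one (value 1 in each assay) called as many, 34 genes and 21 microRNAs against a highest of 0 and 0 in the others, so chance can be excluded for the counts (1 of 32) only as far as the stages are independent. Some stage differences were correlated, with r up to 0.60 in mRNA and 0.76 in small RNA, while other pairs went down to −0.28 and −0.003. Neither a culture effect shared by stages nor a difference between the lines unrelated to ADAR is excluded. The 8 ways of swapping protocols within day and line were too few for a share under 0.05. The real split called 116 genes against a highest other of 35 (1 split called as many, the real one included). It called 63 microRNAs against a highest other of 107 (2 splits called as many, the real one included).

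The difference between lines was tested at day 0 against later stages and in the motor neuron against the forebrain protocol, where limma called 0 genes over all. Adjusted over each list alone, the ADAR family had 1 lower gene at day 0 against later stages (0 under quantile normalization, 1 under median-of-ratios scaling). Between protocols the knockdown difference was higher for 2 forebrain genes, DLX1 (2.97) and DLX2 (2.47). It was higher for 4 HOX and caudal genes, among them HOXD1 (1.84) and HOXD3 (1.33). Of 15 ventral spinal and motor neuron genes 5 were higher, with ISL1 at 1.93. Of 30 mature neuron genes 5 were higher (3 under quantile normalization), with NEFM at 2.11 and NEFL at 1.63. Among glia genes 3 passed, 2 higher and 1 lower. The neural crest list had 1 higher gene. The trophoblast and amnion list had 1 higher gene. Of 14 epidermis genes 4 were lower, with CLDN6 at −2.03 and KRT8 at −1.23. Of 25 mesenchyme genes 12 were lower (10 under quantile normalization and 0 at a pseudocount of 5), with COL1A1 at −1.35 and LGALS1 at −1.29. The choroid plexus list had 2 lower genes. Interferon-stimulated genes had 3 lower members (5 under quantile normalization). Of 25 ribosomal protein genes 23 were lower, a count of 0 in limma under quantile normalization and 0 under median-of-ratios scaling. The retinoic acid and BMP-TGFb list had 3 lower genes (3 lower and 1 higher under quantile normalization). In small RNA, 3 epithelial microRNAs were higher at day 0 against later stages, miR-429 (1.86), miR-200a-3p (1.79) and miR-200a-5p (1.46). Under quantile normalization or median-of-ratios scaling 0 passed. The epithelial list median itself did not shrink, at 0.40 as deposited and 0.48 and 0.41 under these scalings. The muscle list had 1 higher microRNA, miR-1 (1.80).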

How the results depend on the processing

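The alternatives without X-linked genes, without both forebrain stages, and with other small RNA totals were chosen after the data were seen; the others were set before. Where no cause is given, the cause was not tested. Counts within 1.5 times the main count are not repeated: 179 of 243 counts that answer a comparison stayed within it. Of the values of single named genes, 1731 kept direction and side of the threshold, 300 kept the direction only, 8 passed newly and 4 reversed.

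Reversals came from leaving out a day 35 stage: TTR between protocols went from −3.08 to 0.031 (range −6.20 to 0.031 over the stages left out), and miR-204-5p from −2.67 to 0.21 (range −5.56 to 0.21), since only day 17 then carried the comparison.

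Under camera with an estimated correlation the called gene lists went from 18 to 0 for the knockdown, 13 to 0 for day 10, 15 to 0 for day 35, 9 to 1 between protocols, 4 to 0 for day 0 against later stages and 14 to 0 for the protocol interaction. The microRNA lists went from 10, 4, 10, 7, 7 and 6 to 0, 0, 0, 1, 0 and 0.

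A pseudocount of 5 gave 75 genes between protocols (main 116), 1 for day 0 against later stages (main 0) and 3 knockdown microRNAs (main 21). The filter at 5 gave 55 knockdown genes (main 34). No filter gave 5 knockdown microRNAs and 3 for day 0 against later stages (main 0). Without the stage block 16 knockdown genes and 0 microRNAs were called by limma. Without both forebrain stages, with fewer samples, these were 2 and 1. Without X-linked genes, with fewer genes, 13 were called. Between protocols the 63 microRNAs became 32 under quantile normalization, 32 under median-of-ratios scaling, 32 with edgeR, 36 without miR-10a and miR-10b and 186 over listed microRNAs. The 21 knockdown microRNAs became 5 under median-of-ratios scaling and 92 with DESeq2.

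Leaving out each stage, with fewer samples, gave 9 to 64 knockdown genes, 30 to 116 genes between protocols, 0 to 348 for the protocol interaction, 1 to 51 knockdown microRNAs, 12 to 302 microRNAs between protocols and 0 to 48 for their interaction.

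At single stages a pseudocount of 0.1 gave 144 genes at day 0 (main 94). A pseudocount of 5 gave 25, 41, 158, 48, 515 and 176 genes at the 6 stages in order, and 18, 29, 46 and 46 microRNAs at day 0, day 10, day 17 motor neuron and day 35 motor neuron. A floor of 1 gave 149 genes at day 0, 588 at day 17 forebrain and 234 at day 17 motor neuron. Quantile normalization gave 58 genes at day 0. Of the 34 knockdown genes 32 were shared under quantile normalization and 26 at a pseudocount of 5, and of the 21 microRNAs 15 and 3. No paired analysis beyond the stage block was possible because each stage held 1 library per line. One read, 0.0631 to 0.166 RPM, limits what small RNA can show; the read depth of the mRNA libraries is unknown.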

Other observations

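The test of mesenchyme genes in this part was chosen after the result was seen, and its verdict was changed after the members were seen; the values on microRNAs inside X-linked stretches and on the microRNA share were also looked up after the calls.

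MicroRNAs inside or beside X-linked genes of the knockdown comparison followed their neighbours in part. In CHM, which was higher, miR-361-5p was higher by 1.36 and miR-361-3p stood at 0.72 (adjusted p = 0.0516). Within the IDS to MTMR1 stretch miR-2114-5p stood at 0.91 (adjusted p = 0.0552). The 7 microRNAs between PHF6 and MOSPD1, where the genes were lower, had a median of −0.04 (−0.25 to 0.17) and 0 were called by limma. The 7 microRNAs in HTR2C, a serotonin receptor gene, were all negative (median −1.40), with miR-1298 at means of 3622 RPM in WT and 899 RPM in the knockdown line (−1.81) and miR-448 at −1.78, and 0 were called by limma.

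Shares were taken over the 12854 genes and 798 microRNAs whose difference was not 0 at any stage. Differences with the same sign at all 6 stages were found for 11.2% of these genes (551 higher and 893 lower) and 17.3% of these microRNAs (112 higher and 26 lower). The median of all microRNAs was 0.11 higher in the knockdown line, and the split of 112 and 26 was not rescaled for this. The differences at some stages were correlated, most between the day 17 stages (r = 0.60 in mRNA and 0.76 in small RNA). The lowest r was −0.28 in mRNA (day 0 with day 35 motor neuron) and −0.003 in small RNA (day 0 with day 35 forebrain). Since stages were not all independent, no share expected by chance is given. Listed microRNAs took a larger share of the small RNA total in the knockdown library at 6 of 6 stages. The difference was 4.84 points on average (SD 3.77, range 2.16 to 12.1) and 3.38 without day 35 forebrain. The exact sign-flip p was 0.0312, the smallest that 6 stages can give, and it takes the stages as independent.

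Mesenchyme genes in the day 35 forebrain knockdown library stood 0.15 (log2, median of 25) above the highest WT library from day 10 on, and 14 of the 25 stood above it, such as SPARC (315 against 155) and LUM (12.9 against 3.39), while S100A6 stood below (0.75 against 9.42). A culture at an earlier stage may account for part of this, but since members went both ways the test did not decide it.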
